A study of Mus musculus with 9 samples.

How the data were processed

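The data were 9 libraries from the retinal pigment epithelium and choroid of mice with laser-induced choroidal neovascularization, 3 each from eyes injected with Fc, ABTAA or VEGF Trap. Per the labels' protocols, burns were made with a laser of 532 nm, 250 mW, 100 ms and 50 µm spot size, burns without a bubble and spots with bleeding were excluded, and the reagents were given at 5 mg/ml. Tissue of 2 times the lesion diameter was cut from flat mounts by laser capture, and 500 ng of total RNA entered LEXOGEN QuantSeq libraries, a kit that reads the 3 prime ends of transcripts. The deposited tables hold whole-number counts per gene symbol, not normalized, and per the submitters' processing notes the tools were Bowtie2 and edgeR with the mm10 build. Versions, the annotation, the counting tool, its strand setting and the treatment of reads with several matches are not given in the sources used here. Groups were taken from the sample titles. The column headings of the Fc tables carry a name for controls of a knockout, which differs from the titles.

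Each table held 24421 symbols and 0 lines without a gene name. Total counts ran from 6335805 to 14439835 per library. In single libraries 15968 to 16996 genes were detected, and the ribosomal precursor Rn45s held 10.05% to 15.82% of counts. Of 14167 genes with a count in every library, 1616 (11.4%) had only even counts, where 28 would if parity were random, and 422 had only multiples of 3. The all-even genes held 14.2% of counts. Such a pattern arises where a read is entered more than once, which makes the counting error larger than the counts show, and 2174 tested genes shared a divisor above 1. Each library was kept as a replicate by its label, and no source ties it to an animal. The 9 pairs of libraries of 1 group had a chi-square per degree of freedom of 8.5 to 20.6 against counting noise, which reads entered more than once also raise.

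Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test) in R 4.3.3, with all 9 libraries in 1 model of 6 residual degrees of freedom. This left 14054 genes, with a biological coefficient of variation of 17.9% and a median standard error of 0.20 on the log2 scale. Contrasts were ABTAA minus Fc, VEGF Trap minus Fc and ABTAA minus VEGF Trap, adjusted by Benjamini-Hochberg within each, with a threshold of 0.05. A standard error is the log2 fold change divided by the square root of F, and intervals are at 95%. CPM are TMM-scaled, with SD over 3 libraries. No pseudocount beyond the default of edgeR was used.

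The design, the alternatives and 26 gene lists were fixed before the data were examined. The lists were endothelial cell, tip cell and sprouting, angiopoietin-Tie signalling, VEGF ligands and receptors, junction and barrier, pericyte and smooth muscle, retinal pigment epithelium, melanocyte and pigment, photoreceptor, inner retina, lens, skeletal muscle, ocular surface epithelium, erythrocyte, Schwann cell, macrophage and microglia, lymphocyte and neutrophil, inflammatory cytokine and adhesion, interferon response, complement, fibrosis and extracellular matrix, hypoxia and glycolysis, proliferation, immediate early and stress, oxidative phosphorylation, and cytosolic ribosomal protein. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists within each contrast, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Named genes were, for each comparison, the 12 largest increases and the 12 largest decreases among genes past the threshold with at least 10 CPM in the higher group, no overlap between the libraries of the groups and an established symbol, or, with fewer than 10 genes past the threshold, the 10 smallest p-values. Up to 4 called members of each list, and a fixed set of Tie2, VEGF, endothelial, pigment epithelium and macrophage genes, were added. Some genes that this rule names are not reported here. Klf2, Nos3, Des, Cxcl1, Cxcl2, Il1b, Cryaa and Crygd were chosen after their values were seen.

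Coordinates came from GENCODE M21 on GRCm38, the build that mm10 names. Of the symbols, 23384 matched directly, 670 by an older symbol, and 367 did not match. The last 200 bases of each transcript were searched against all others with BLAST+ 2.17.0, and a match of at least 100 bases at 95% identity counted as a copy. Of tested genes, 1661 had one and 4533 overlapped an exon on the other strand. The search covered both strands, so a copy can be an overlapping gene on the other strand, as Ube2c is for Tnnc2.

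Fixed alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, library totals alone, no filter, a filter of 10 counts in 6 libraries, a fit of only the compared groups, the replicate number as a block, a test against a fold of 1.2, and the omission of each library in turn. The filter was run again for each omission, so the measured members of a list can differ from those of the main fit. Alternatives chosen after seeing the data were division by the common divisor, omission of Rn45s, the log2 summed CPM of the skeletal muscle list as a covariate, and corrections for GC content, GC content of the last 400 bases and length, each by a lowess trend of span 0.3 per library. The steps were tested on simulated data for ABTAA against Fc, with 14054 genes of which 200 were changed, in 5 runs. Of the changed genes 20.7% were recovered at 1.5-fold, 62.8% at 2-fold and 82.4% at 3-fold, with 6.6% false calls. A list shifted 1.3-fold was called in 5 of 5 runs with the preset correlation and in 5 with an estimated one. Lists that were not shifted as a whole were called 0 to 2 times per run (mean 1) with the preset correlation, among them lens in 2 runs, and 0 times with an estimated one. Of these 5 false or partial calls, 1 was of a list that shares genes with the shifted list. Genes were drawn independently in these simulations, so the recovery and false calls do not cover genes that vary together. The measured endothelial list had an estimated correlation of 0.331 for ABTAA against Fc.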

Results

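Gene expression was measured in laser-induced choroidal neovascularization (CNV), a mouse model in which a laser burn ruptures the Bruch membrane and new vessels grow from the choroid. Male mice of 8 weeks received 4 burns per eye and an intravitreal injection of 5 µg of 1 of 3 reagents. These were Fc, an antibody fragment used as the control, ABTAA, an antibody that binds angiopoietin 2 and activates the endothelial receptor Tie2, and VEGF Trap, a soluble decoy receptor for VEGF. The CNV and a margin of retinal pigment epithelium and choroid were cut out by laser capture microdissection, and RNA was sequenced from its 3 prime ends. Each group held 3 libraries. Total counts were 10669772, 11563695 and 12326569 for Fc 1, 2 and 3, 9883151, 10060014 and 6335805 for ABTAA 1, 2 and 3, and 12775062, 14439835 and 7346988 for VEGF Trap 1, 2 and 3. At these depths a floor of 3 counts corresponded to 0.209 to 0.469 CPM (counts scaled to library size), which covers counting error only. No label ties a library to an animal, so p-values measure only the spread between these samples, which may be technical. The Fc libraries were assigned by their titles, although the column headings of their tables carry a name for controls of a knockout.

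The comparison of ABTAA with Fc asks how Tie2 activation changes expression in the lesion. In ABTAA libraries, some endothelial genes stood higher than in Fc. Of 23 measured endothelial genes, 5 rose, 0 fell and 18 did not pass the test over all genes. Plvap, which forms the diaphragms of fenestrated capillaries, rose from 70.3 ± 10.6 to 125 ± 10.2 CPM (SD, n = 3 per group), a log2 fold change of 0.83 ± 0.13 (SE, adjusted p = 0.0117, edgeR). Eng, a TGF-beta co-receptor of endothelial cells, rose from 263 ± 37.3 to 454 ± 42.8 CPM (0.79 ± 0.12, adjusted p = 0.00872). Cldn5, an endothelial tight junction protein, rose by 0.87 ± 0.14 (adjusted p = 0.0123), Egfl7 by 0.55 ± 0.11 (adjusted p = 0.0359) and the adhesion molecule Pecam1 by 0.45 ± 0.10 (adjusted p = 0.0473). In mm10 (GRCm38) these genes lie on chromosome 8 from 71497765 to 71511752 (Plvap), chromosome 2 from 32646595 to 32682669 (Eng), chromosome 16 from 18776847 to 18778262 (Cldn5), chromosome 2 from 26580014 to 26593120 (Egfl7) and chromosome 11 from 106654217 to 106750628 (Pecam1). Adjusted over the list alone, 9 endothelial genes were higher. The list had a median log2 fold change of 0.34 and an adjusted p of 1.68e-09 by camera with a preset correlation, and adjusted p = 0.307 with an estimated correlation. The Tie2 gene Tek (0.34 ± 0.24, adjusted p = 0.511), Tie1 (-0.07 ± 0.24), Angpt1 (0.26 ± 0.10, adjusted p = 0.203), Angpt2 (0.30 ± 0.23), Kdr (0.20 ± 0.14), Flt1 (0.23 ± 0.15), Cdh5 (0.28 ± 0.15), Vegfa (-0.07 ± 0.14) and Pgf (0.50 ± 0.15, adjusted p = 0.0975) did not pass. Neither did the pigment epithelium gene Rpe65 (0.38 ± 0.18) or the macrophage marker Adgre1 (-0.12 ± 0.15). Summed CPM of the endothelial list was 2118 to 2706 in Fc and 3215 to 3380 in ABTAA, and that of the skeletal muscle list was 108 to 165 and 241 to 488 in the same libraries. Over all genes, 0 endothelial genes passed without Fc 2 or without ABTAA 2, 1 without Fc 3 and 3 without ABTAA 1, and 2 passed after a correction for GC content and 3 with GC content of the 3 prime end, while the camera call held in each.

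**Figure D1:**
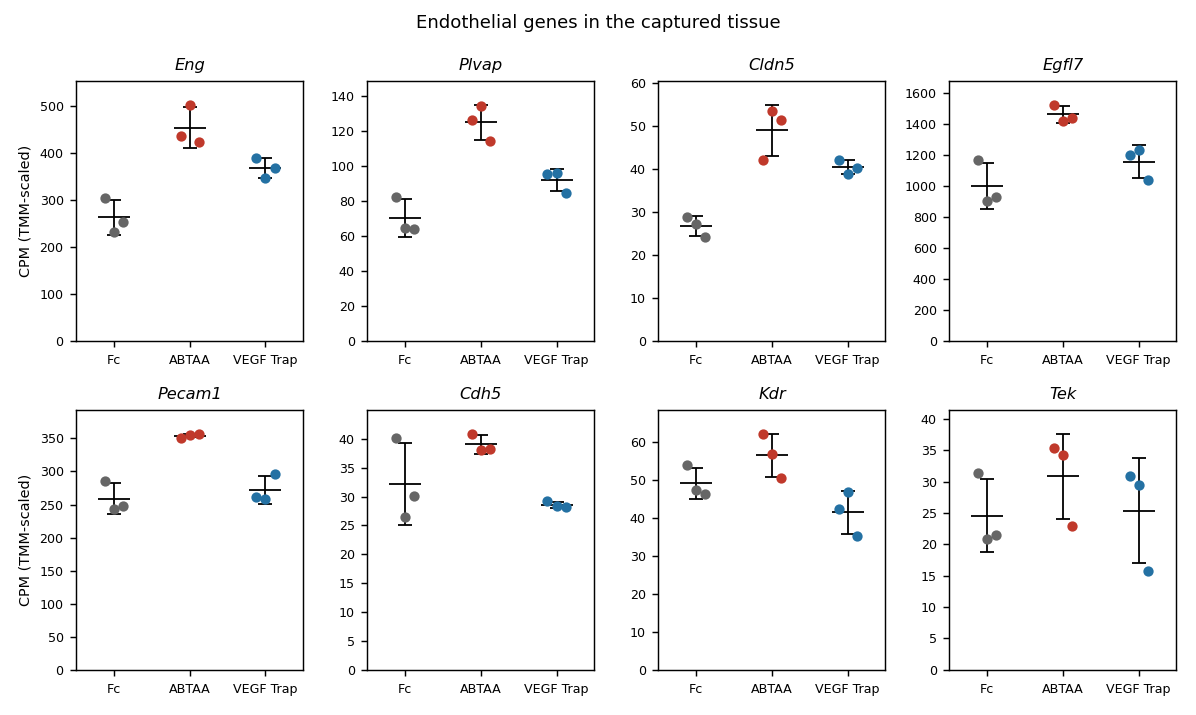
Normalized expression (CPM, TMM-scaled, linear axes from 0) of 8 endothelial genes in the 3 groups. Points are single libraries (n = 3 per group), long bars are means and whiskers are SD. For Eng, Plvap, Cldn5, Egfl7 and Pecam1, every ABTAA library lay above every Fc library.

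Among the named genes, those of skeletal muscle had the largest increases in ABTAA. Of 14 measured skeletal muscle genes, 8 rose and 6 did not pass, and 12 were higher adjusted over the list alone. Acta1, the skeletal muscle actin, rose from 23.8 ± 2.25 to 88.8 ± 38.7 CPM (log2 1.90 ± 0.32, adjusted p = 0.0148, edgeR), and the muscle creatine kinase Ckm from 3.26 ± 1.47 to 14.5 ± 4.76 CPM (2.16 ± 0.32, adjusted p = 0.00872). Tnnc2, Pvalb, Mylpf and Atp2a1 of the same list and Tcap, Xirp2 and Tnnt2 outside it also rose, by 1.19 to 1.93. The list had a median of 1.41 and an adjusted p of 3.95e-21 by camera, and adjusted p = 0.307 with an estimated correlation. Among 15 pericyte and smooth muscle genes 0 passed over all genes and 2 were higher adjusted over the list alone (median 0.35, camera adjusted p = 0.00395, and adjusted p = 0.309 with an estimated correlation). Desmin, Des, stood at 0.86 ± 0.21 (adjusted p = 0.0568). Of 11 melanocyte genes, Pmel, which builds melanosome fibrils, rose by 0.95 ± 0.13 (adjusted p = 0.00872), and 3 were higher adjusted over the list alone (median 0.33, camera adjusted p = 0.00112, and adjusted p = 0.307 with an estimated correlation). Of 12 angiopoietin-Tie signalling genes 0 passed and 1 was higher adjusted over the list alone (median 0.27, camera adjusted p = 0.0175, and adjusted p = 0.307 with an estimated correlation). The shear-responsive factor Klf2 stood at 0.61 ± 0.15 (adjusted p = 0.0616) and Nos3 at 0.65 ± 0.25 (adjusted p = 0.196). The 8 skeletal muscle genes became 5 without Fc 1, 0 without Fc 2, 3 without Fc 3, 0 without ABTAA 2 and 5 without ABTAA 3. Pmel did not pass without ABTAA 2, the pericyte call ended without Fc 1 (adjusted p = 0.0736), and the angiopoietin-Tie call without Fc 2 (0.0564, median 0.145) or Fc 3 (0.0741), with a median of 0.175 without ABTAA 3.

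Of 21 macrophage and microglia genes in the ABTAA comparison, the Fc receptor Fcgr3 fell by 0.67 ± 0.13 (adjusted p = 0.032, edgeR) and the complement chain C1qb by 0.55 ± 0.13 (adjusted p = 0.0473), while 19 did not pass. Adjusted over the list alone, 8 were lower. The list had a median of -0.27 and a camera adjusted p of 8.12e-07, and adjusted p = 0.307 with an estimated correlation. The neutrophil gene S100a9 fell from 95.6 ± 88.5 to 17.6 ± 6.27 CPM (log2 -2.43 ± 0.50, adjusted p = 0.035), and 1 of 6 lymphocyte and neutrophil genes passed, 2 when adjusted over the list alone (median -0.36, camera adjusted p = 0.0226, and adjusted p = 0.309 with an estimated correlation). S100a9 did not pass without Fc 1 (log2 -1.34), without any 1 ABTAA library or after the correction for GC content, and the list median ran from -2.167 to -0.204 without single libraries, with a camera adjusted p of at most 0.046. The filter was run again for each, so the measured members may differ from the 6. Summed CPM of that list was 515 in Fc 1 and 47.4 to 142 in the other libraries. Of 20 inflammatory cytokine and adhesion genes 0 passed, also when adjusted over the list alone (median -0.35, camera adjusted p = 0.0175, and adjusted p = 0.527 with an estimated correlation). Of 16 hypoxia and glycolysis genes 0 passed, and 1 was higher and 3 lower adjusted over the list alone (median -0.27, camera adjusted p = 0.0342, and adjusted p = 0.307 with an estimated correlation). The 2 called macrophage genes became 0 without Fc 1, 2 or 3 or without ABTAA 2, and 1 without ABTAA 1, ABTAA 3, VEGF Trap 2 or VEGF Trap 3. The cytokine call ended without Fc 1 (adjusted p = 0.529, median -0.132), ABTAA 2 (0.0711, median -0.176) or ABTAA 3 (0.0522), with a median of -0.594 without ABTAA 1, and the hypoxia call without Fc 1 (0.0796), Fc 2 (0.0564) or ABTAA 2 (0.0644). With the skeletal muscle total as a covariate, the endothelial and macrophage lists still passed by camera (adjusted p = 0.0435 for both). Their medians were 0.197 after 0.34 and -0.131 after -0.27, and with an estimated correlation 0 lists passed (lowest adjusted p = 0.808). The other calls ended under this covariate, apart from the skeletal muscle list, which its own total cannot test.

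**Figure D2:**
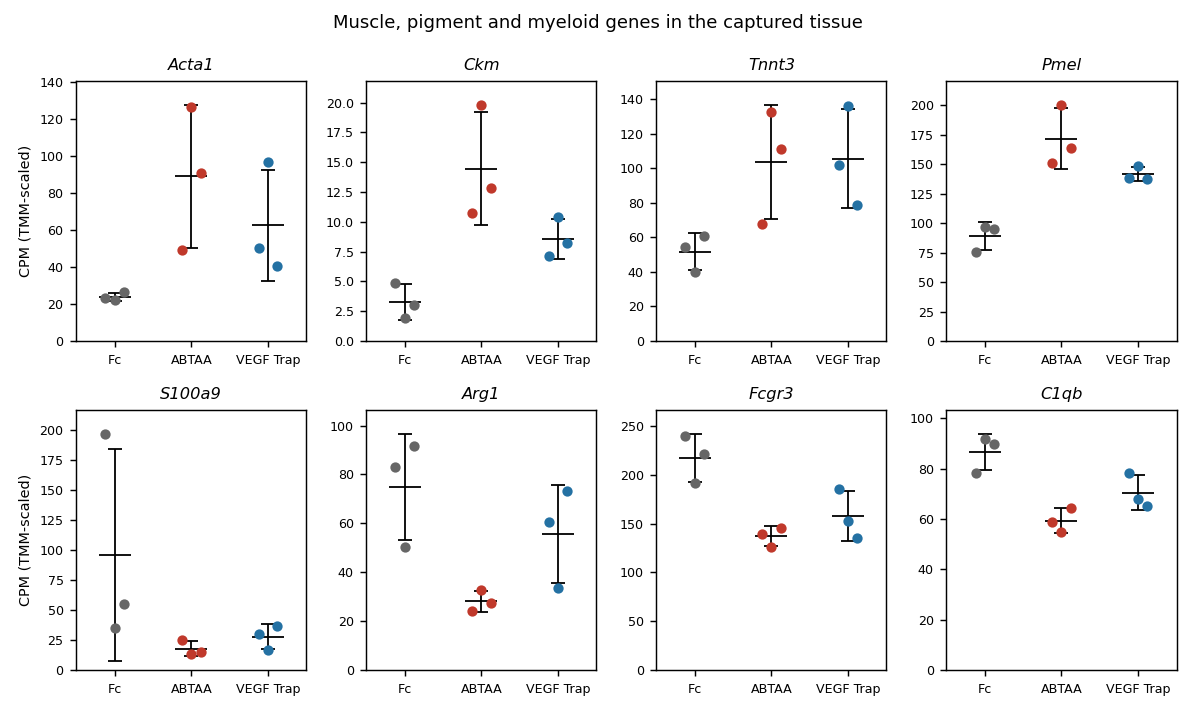
Normalized expression (CPM, TMM-scaled, linear axes from 0) of 4 muscle and pigment genes and 4 myeloid genes in the 3 groups. Points are single libraries (n = 3 per group), long bars are means and whiskers are SD. Fc 1 sets most of the S100a9 mean of 95.6 CPM.

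Several single genes outside these lists fell in ABTAA. Rraga, a Rag GTPase of amino acid sensing, fell from 105 ± 15.2 to 40.9 ± 15 CPM (log2 -1.37 ± 0.20, adjusted p = 0.00872, edgeR). Pomp, a proteasome assembly factor, fell from 295 ± 13.2 to 151 ± 26.4 CPM (-0.97 ± 0.13, adjusted p = 0.00872), and the macrophage-expressed arginase Arg1 from 75 ± 21.8 to 28.1 ± 4.17 CPM (-1.42 ± 0.26, adjusted p = 0.0216). Lrpprc, a stabilizer of mitochondrial mRNAs, Lig4, Nfkbib, Pid1, Rasl11b, Snhg1 and St3gal5 fell by 0.86 to 1.19. The ribosomal protein gene Rps23 (-0.80), Ndufb3 (-0.65) and Cox7c (-0.66) fell, each within a list that was not called. Pianp rose from 14.8 ± 3.86 to 36.7 ± 1.99 CPM, and Tbx1 (1.40), Tjp3 (1.16), Col6a1 (0.62) and C4b (0.58) rose as well. Over 14054 tested genes, 197 changed in ABTAA against Fc, 119 higher and 78 lower, and library totals without TMM scaling gave 66 higher and 106 lower. The higher genes had a median GC content of 56.1% and the lower genes 46.6%. An unadjusted p under 0.05 was found for 2370 genes, where chance gives 703, and 23.05% of tested genes had no overlap between the groups, where chance gives 10%. The count of 197 became 47, 13 and 35 without Fc 1, 2 and 3, 58 and 0 without ABTAA 1 and 2 (1743 genes at an unadjusted p under 0.05), and 373 and 101 without VEGF Trap 1 and 2, and 0 of the 37 named calls held without each library in turn. It was 750 with DESeq2, 411 with limma-voom, 684 without a filter, 301 with only the compared groups, 71 after a correction for GC content, 131 with GC content of the 3 prime end, 10 against a fold of 1.2, and 0 with the skeletal muscle total as a covariate (967 at an unadjusted p under 0.05), where the 197 genes had a median absolute log2 fold change of 0.64 after 0.68 and a median SE of 0.26 after 0.14.

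The comparison of VEGF Trap with Fc asks the same of VEGF blockade. A few pigment and skeletal muscle genes rose, 2 of 11 melanocyte and 3 of 14 skeletal muscle genes, and no endothelial gene passed. Tyr, the tyrosinase of melanin synthesis, rose from 8.93 ± 2.11 to 20.3 ± 4.26 CPM (SD, n = 3 per group, log2 1.19 ± 0.27, adjusted p = 0.0478, edgeR), and Pmel from 89 ± 11.7 to 142 ± 6.16 CPM (0.67 ± 0.13, adjusted p = 0.0322). Acta1 rose by a log2 fold change of 1.40 ± 0.31 (adjusted p = 0.0466), which was 0.93 without VEGF Trap 2. Atp2a1 rose by 1.06 and the fast troponin Tnnt3 by 1.03. Rraga fell from 105 ± 15.2 to 33.9 ± 1.31 CPM (-1.63 ± 0.20, adjusted p = 0.0058). Unc5c, a netrin receptor, fell by 1.78 ± 0.32 (adjusted p = 0.0263) and Lars2, a mitochondrial leucyl-tRNA synthetase, by 1.88 ± 0.41 (adjusted p = 0.0428), with an Fc mean of 91.2 ± 56 CPM. In mm10 (GRCm38), Rraga lies on chromosome 4 from 86575668 to 86577285, Pmel on chromosome 10 from 128704195 to 128720238 and Tyr on chromosome 7 from 87424771 to 87493512. Lrpprc, Lig4, Spag7, Snhg1, Exosc9, Eif2s3x, Foxred1 and D17H6S56E-5 fell by 0.96 to 1.27, as did Rps23 (-0.81) and Ndufb3 (-0.69). Nmral1, Pianp, Pacsin1, Crocc, Slc4a3, Slc16a9, Tmem53 and Npnt rose by 0.89 to 1.15, and C4b by 0.56. Pecam1 (0.07 ± 0.10), Plvap (0.39 ± 0.13, adjusted p = 0.139), Cdh5 (-0.17 ± 0.15), Kdr (-0.24 ± 0.14), Flt1 (0.06 ± 0.14), Vegfa (-0.01 ± 0.14), Pgf (0.44 ± 0.15), Tek (0.06 ± 0.24), Tie1 (0.03 ± 0.24), Angpt1 (0.18 ± 0.10), Angpt2 (-0.20 ± 0.23), Rpe65 (0.46 ± 0.18) and Adgre1 (0.25 ± 0.15) did not pass.

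By list, 3 of 14 skeletal muscle genes rose in VEGF Trap and 9 were higher adjusted over the list alone (median 1.03, camera adjusted p = 3e-11). Of 11 melanocyte genes 2 rose, 3 adjusted over the list alone (median 0.20, adjusted p = 0.00763). Of 20 tip cell and sprouting genes 0 passed, and adjusted over the list alone 1 was higher and 3 lower (median -0.23, adjusted p = 0.0342). Of 17 proliferation genes 0 passed and 2 were lower adjusted over the list alone (median -0.23, adjusted p = 0.0158). Of 8 lens crystallin and fibre genes 0 passed and 4 were higher adjusted over the list alone (median 1.82, adjusted p = 0.0367). Each of these 5 lists had adjusted p = 0.863 with an estimated correlation. The endothelial list had a median of 0.12 (adjusted p = 0.0912), 0 called genes and 2 adjusted over the list alone, and was called without Fc 1 (median 0.221, adjusted p = 0.000246, and adjusted p = 0.688 with an estimated correlation) or VEGF Trap 3 (median 0.169, adjusted p = 0.0047, and adjusted p = 0.833 with an estimated correlation). The lymphocyte and neutrophil list had a median of -0.57 (adjusted p = 0.0979), 0 of 6 called genes and 2 lower adjusted over the list alone. It was called without each library in turn except Fc 1 or Fc 3 (medians -1.602 to -0.867, adjusted p of 1.19e-06 to 0.0372, and adjusted p of 0.394 to 0.881 with an estimated correlation) and with the replicate number as a block (0.0379, and adjusted p = 0.618 with an estimated correlation). The filter was run again without each library, so these calls may rest on other members than the 6. Without ABTAA 1, which is not compared here, the median was already -1.331. Summed CPM of the lens list was 150 in VEGF Trap 1 and 16.6 to 48.1 in the other libraries, and that of the photoreceptor list was 334 and 90.8 to 225. Called muscle genes were 0 without Fc 1, Fc 2, ABTAA 3, VEGF Trap 2 or VEGF Trap 3 and 1 without Fc 3 or VEGF Trap 1, and also 0 with library totals or either correction for GC content and 1 with the length correction. Called melanocyte genes were 0 without any 1 Fc or VEGF Trap library and 1 without ABTAA 1 or with library totals (median 0.119). The lens call ended without VEGF Trap 1 (adjusted p = 0.369, median 0.656), Fc 2 (0.19) or Fc 3 (0.0565) and after the correction for GC content (0.0552), the proliferation call without VEGF Trap 1 (0.344, median -0.123), the tip cell call without Fc 1 (0.295) or VEGF Trap 3 (0.13), and the melanocyte call without Fc 1 (0.104, median 0.102). The melanocyte median was 0.305 without Fc 2, the proliferation median -0.109 without Fc 2 and -0.379 without VEGF Trap 3, and 1 lens gene passed without VEGF Trap 2 and 3 with the replicate number as a block. With the skeletal muscle total as a covariate, the melanocyte (0.158), tip cell (0.109) and proliferation (0.158) calls ended.

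In all, 144 genes changed in VEGF Trap against Fc by edgeR, 72 higher and 72 lower, and library totals without TMM scaling gave 39 higher and 182 lower. The higher genes had a median GC content of 55.6% and the lower genes 48.7%. An unadjusted p under 0.05 was found for 2162 genes against 703 by chance, and 20.86% of tested genes had no overlap between the groups, where chance gives 10%. The count became 18, 7 and 32 without Fc 1, 2 and 3 and 62, 60 and 25 without VEGF Trap 1, 2 and 3, and of the 28 named calls only Rraga and D17H6S56E-5 held without each library in turn. It was 671 with DESeq2, 242 with limma-voom, 616 without a filter, 249 with counts divided by their common divisor, 2 against a fold of 1.2 and 0 with the skeletal muscle total as a covariate (1368 at an unadjusted p under 0.05), where the 144 genes had a median absolute log2 fold change of 0.71 after 0.69 and a median SE of 0.22 after 0.14.

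The direct comparison of ABTAA with VEGF Trap asks whether Tie2 activation and VEGF blockade differ. No single gene was shown to differ. By camera with a preset correlation, vessel lists stood higher and the macrophage list lower in ABTAA, and with an estimated correlation 0 of 26 lists passed. By edgeR 0 genes passed, with 711 at an unadjusted p under 0.05 where chance gives 703 and a smallest adjusted p of 0.851. DESeq2 called 1, limma-voom 0, and the edgeR test without a filter 30. Pecam1 was 354 ± 2.97 CPM in ABTAA and 272 ± 20.7 in VEGF Trap (SD, n = 3 per group), a log2 difference of 0.38 with a 95% interval of 0.16 to 0.60 (adjusted p = 0.852). Plvap differed by 0.44 (0.17 to 0.71), Kdr by 0.44 (0.15 to 0.74), Cdh5 by 0.45 (0.12 to 0.78), Angpt2 by 0.50 (0.01 to 0.99) and Tek by 0.27 (-0.23 to 0.78), with adjusted p of 0.932 to 0.965. Tie1 differed by -0.10 (-0.62 to 0.41), Angpt1 by 0.08 (-0.14 to 0.29), Flt1 by 0.17 (-0.14 to 0.48), Vegfa by -0.06 (-0.35 to 0.24), Pgf by 0.06 (-0.25 to 0.37), Rpe65 by -0.08 (-0.47 to 0.31) and Adgre1 by -0.37 (-0.69 to -0.05), with adjusted p of 0.956 to 0.987. The smallest unadjusted p-values belonged to Ncmap (1.21), Calr4 (-1.42), Fetub (1.95), the lymphoid GTPase Gimap4 (0.98), Ccr9 (-1.45), the lactate transporter Slc16a3 (-0.57), Ndrg3 (0.83), the basement membrane collagen Col4a2 (0.65), Foxred1 (0.76) and Slc9a3r2 (0.57), none of them past the threshold.

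Of the fixed lists, 10 were called by camera between ABTAA and VEGF Trap, and 0 of their genes passed over all genes. Medians were higher in ABTAA for endothelial (0.28, adjusted p = 3.63e-08, 6 of 23 higher adjusted over the list alone), tip cell (0.14, adjusted p = 5.65e-05, 4 of 20), pericyte and smooth muscle (0.32, adjusted p = 1.13e-05, 0 of 15), junction and barrier (0.24, adjusted p = 0.00434, 0 of 13), angiopoietin-Tie (0.13, adjusted p = 0.0138, 0 of 12), skeletal muscle (0.45, adjusted p = 6.57e-05, 0 of 14) and proliferation genes (0.25, adjusted p = 9.2e-05, 0 of 17). They were lower for macrophage and microglia (-0.23, adjusted p = 1.9e-07, 0 of 21), hypoxia and glycolysis (-0.15, adjusted p = 0.000773, 0 of 16) and lens genes (-1.63, adjusted p = 0.00375, 4 of 8 lower). All 17 proliferation genes had a positive and all 21 macrophage genes a negative fold change. The vessel lists are not all separate results. Also in another list were 7 of 23 endothelial, 6 of 20 tip cell, 3 of 12 angiopoietin-Tie and 3 of 13 junction and barrier genes, and 0 of 15 pericyte and smooth muscle genes. The lowest value for these 10 lists was adjusted p = 0.19 with an estimated correlation, for hypoxia and glycolysis, and endothelial genes had adjusted p = 0.27 with an estimated correlation. Summed muscle CPM was 223 to 393 in VEGF Trap and 241 to 488 in ABTAA. The lens and proliferation calls ended without VEGF Trap 1 (adjusted p = 0.142 and 0.0734), the lens and skeletal muscle calls without ABTAA 2 (0.0671 for both), and the angiopoietin-Tie call without ABTAA 2 (0.0557) or VEGF Trap 3 (0.1). Without ABTAA 1, medians were 0.027 for tip cell, 0.383 for proliferation, 0.695 for skeletal muscle and -2.719 for lens genes. They were -0.031 for junction and barrier and 0.178 for skeletal muscle genes without ABTAA 2, and 0.204 for pericyte and 0.122 for proliferation genes without ABTAA 3. They were 0.246 for tip cell, 0.209 for pericyte, 0.116 for proliferation and -0.986 for lens genes without VEGF Trap 1, 0.717 for skeletal muscle genes without VEGF Trap 2, and 0.253 for skeletal muscle and 0.409 for proliferation genes without VEGF Trap 3.

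**Figure D3:**
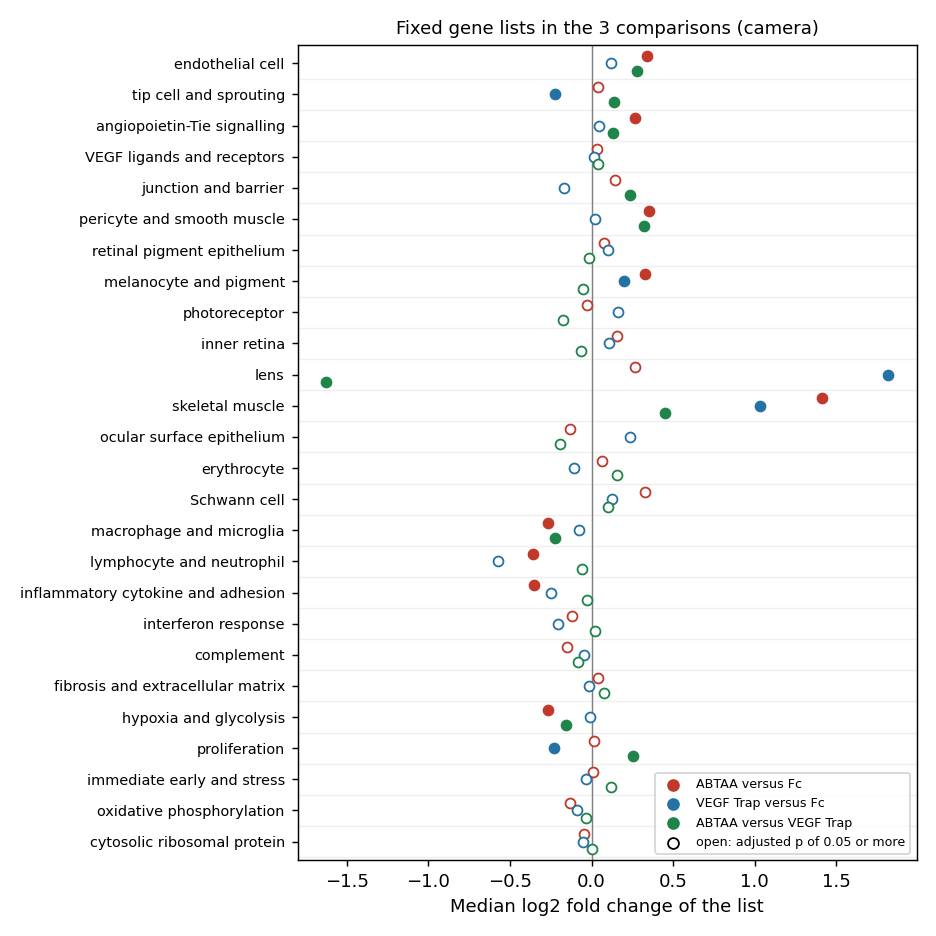
Median log2 fold change of each of the 26 gene lists (horizontal axis) in the 3 comparisons. Filled points are lists past an adjusted p of 0.05 by camera with a preset correlation (9, 5 and 10 lists), open points are not, and 0 lists passed with an estimated correlation.

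Many genes differed from Fc in both treated groups. Of the 197 and 144 genes, 73 changed in both, 36 higher, 37 lower and 0 in opposite directions, where 20 simulations with unchanged groups gave 0 genes in both and independent lists would share 0.61 higher and 0.4 lower genes. The simulations leave out the effects and the independent lists leave out the shared controls. Pianp, Acta1, Atp2a1, Pmel and C4b were higher and Rraga, Lrpprc, Lig4, Snhg1, Rps23 and Ndufb3 lower in both. Across genes, which are not independent replicates, the fold changes had a correlation of 0.612 (jackknife SE 0.215) and a covariance of 0.1156. Both comparisons use the same Fc libraries, and 100 simulations with unchanged groups gave a mean correlation of 0.487 (highest 0.511) and a covariance of 0.0593 (highest 0.0653), which leaves a covariance of 0.0563. The correlation lay within 1 SE of the simulated mean. It was 0.468 without ABTAA 1 and 0.481 without VEGF Trap 2, while the covariance was 0.1991 without Fc 3. No simulations were run with a library left out, so these 3 values have no matching simulated value. The share of genes with the same sign was 75.9%, and 66.4% in the simulations. The 3 Fc libraries cannot give each comparison at least 2 controls of its own, so part of the excess may come from the shared controls. Of the 268 genes changed in either comparison, 58 had an unadjusted p under 0.05 between ABTAA and VEGF Trap.

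**Figure D4:**
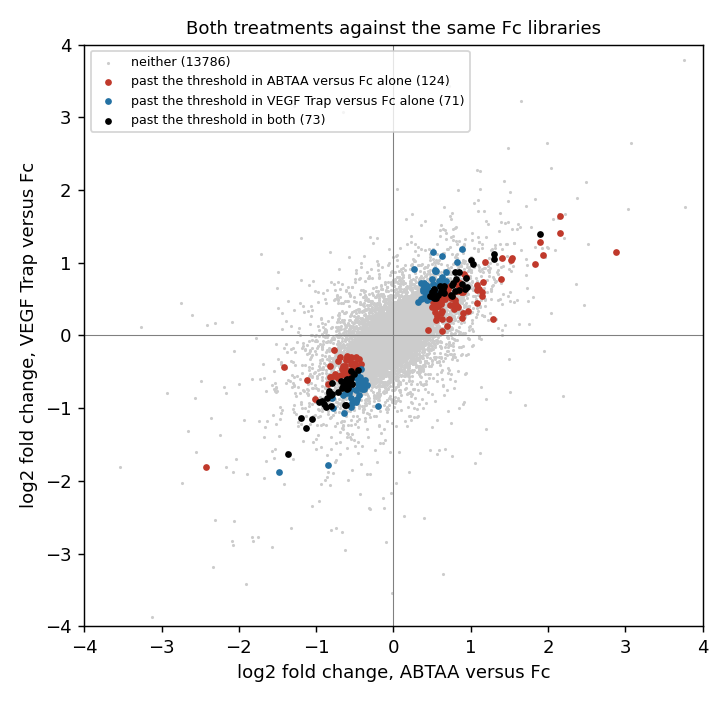
Log2 fold changes of the tested genes in ABTAA versus Fc (horizontal axis) and VEGF Trap versus Fc (vertical axis). Each point is a gene, and colours mark the 124 genes past the threshold in ABTAA alone, the 71 in VEGF Trap alone and the 73 in both. Axes end at 4 in each direction, which leaves out 5 genes, 0 of them changed.

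Some named genes are uncertain because their reads may not belong to them alone. Exons of Eng overlap Fpgs on the other strand, as do those of Egfl7 with Agpat2, Tnnc2 with Ube2c, Atp2a1 with Rabep2, Pmel with Dgka and Cdk2, Nfkbib with Sirt2, Tjp3 with Apba3, Tmem53 with Armh1, Exosc9 with Ccna2, Ccr9 with Slc6a20a and Col4a2 with Col4a1. Ckm, Xirp2, Unc5c and Angpt1 overlap unnamed transcripts on the other strand, and Egfl7 and Snhg1 overlap other transcripts on their own strand. C4b has a near-identical 3 prime end in C4a and Cox7c in Gm10012. Slc16a9 matched Gm9877, which its exons overlap on the other strand, so that match may be the overlap itself. D17H6S56E-5 was not found in the annotation. Counts of Eng, Tek, Vegfa, Tbx1, Tjp3, Foxred1, Fetub and Slc16a3 were multiples of 3 in every library, and those of Acta1, Angpt1, Pgf, S100a9, St3gal5, Unc5c, Xirp2, Crocc, Ccr9, Ndrg3 and Slc9a3r2 were even. Those of Tnnt3 and Pacsin1 were multiples of 4, of Npnt multiples of 5, and of Tmem53 and Ncmap multiples of 6.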

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

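The GC, length, divisor, Rn45s and muscle covariate tests below were chosen only after the results were seen. Counts of changed genes for ABTAA against Fc (197), VEGF Trap against Fc (144) and ABTAA against VEGF Trap (0, with 711 at an unadjusted p under 0.05) depended on the processing as follows. DESeq2 gave 750, 671 and 1, limma-voom 411, 242 and 0, and the test without a filter 684, 616 and 30. Only the compared groups gave 301, 130 and 0, and library totals without TMM 172, 221 and 0. A fold of 1.2 gave 10, 2 and 0. The correction for GC content gave 71, 96 and 0, that for the 3 prime end 131, 138 and 0, and division by the common divisor 284, 249 and 0. The muscle covariate gave 0, 0 and 0 and turned Tcap to -0.083 and Mylpf to -0.198 in ABTAA against Fc. This says nothing of Mylpf, which is part of the muscle total. Tcap is a muscle gene outside the list, and its value cannot be told from the difference that the total shares with the groups. For a fold of 1.2 the stricter hypothesis itself lowers the count, and the muscle covariate takes up a difference it shares with the groups and raised the median standard error of the 73 shared genes from 0.13 to 0.25, while their median absolute log2 fold change went from 0.67 to 0.63. For the others the cause was not tested. RLE scaling, a filter of 10 counts in 6 libraries, omission of Rn45s and the length correction stayed within 1.5 times. Of the 197 calls, 192 were also called by DESeq2, 196 by limma-voom and 189 with RLE scaling, and of the 144, 144, 142 and 144.

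Omission of single libraries gave 0 to 373 genes for ABTAA against Fc, 7 to 144 for VEGF Trap against Fc, and 0 in each case for ABTAA against VEGF Trap. The lowest values came without ABTAA 2 (0) and without Fc 2 (13 and 7), and the highest without VEGF Trap 1 (373). All these fits had fewer libraries, and without ABTAA 1 or ABTAA 3 the counts for ABTAA against Fc were 58 and 145. Of the named calls, 33 of 37 and 22 of 28 held under DESeq2, limma-voom, RLE and library totals, and 0 of 65 held in every setting. Lists called by camera numbered 9, 5 and 10. With an estimated correlation 0, 0 and 0 were called, and by fry, which asks only whether a list moves 1 way, 0, 0 and 0, with lowest adjusted p of 0.053, 0.429 and 0.0669. With library totals, omission of Rn45s and either GC correction, fry called macrophage and hypoxia for ABTAA against Fc and hypoxia for ABTAA against VEGF Trap, and without single libraries 0 to 4, 0 and 0 to 1 lists. In its mixed form, which asks whether members move in either direction, fry called 14, 6 and 1. With the muscle covariate 2 lists were called for VEGF Trap against Fc, lens as the only 1 of the 5 (adjusted p = 0.000383) and interferon response as a new call, and 6 for ABTAA against Fc, 2 of the 9 and 4 new. The covariate turned the median of the pericyte list to -0.067 for ABTAA against Fc. It turned that of the interferon response list from -0.12 to 0.764 for ABTAA against Fc (camera adjusted p = 1.09e-09, and 0.893 with an estimated correlation). For VEGF Trap against Fc that median went from -0.203 to 0.599 (4e-07, and 0.997 with an estimated correlation). The skeletal muscle list was not judged by the covariate, which is its own total. Omission of single libraries gave 7 to 11, 4 to 7 and 9 to 12. The correlation of fold changes was 0.468 to 0.693 without single libraries and 0.594 to 0.675 in the other settings. Over named genes and settings, 2385 results kept their side of the threshold, 469 were weaker, 15 stronger and 2 reversed. Direction was compared only where the gene passed in the main fit or in the alternative. All weaker results belong to the 65 named calls, while the 2385 include named genes that did not pass in the main fit and could not become weaker. For lists called in the main fit, 421 results kept their call and direction and 83 were weaker.

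Libraries with the same replicate number had correlated deviations of 0.013 to 0.112, other pairs -0.092 to 0.037, and 8 of 9 libraries correlated best with their own number, a hint from the data and not from the design. With the replicate block, 334, 300 and 1 genes were called, and with the replicate block and the GC correction 178, 201 and 1. With the replicate block fry called 4, 0 and 5 lists. For ABTAA against Fc these were pericyte, macrophage, hypoxia and oxidative phosphorylation (adjusted p = 0.034), and for ABTAA against VEGF Trap tip cell, pericyte, lens, macrophage and hypoxia (adjusted p of 0.0438 to 0.0463). An estimated correlation called 0 lists with the block, and 3 lens genes passed for VEGF Trap against Fc, where the main fit had 0. Depth limited genes near the floor, and at a median standard error of 0.20 simulated changes of 1.5-fold were recovered in 20.7% of cases for ABTAA against Fc.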

Other observations

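The tests of GC content, muscle dilution, muscle carry-over, the share of endothelial cells and vessels in muscle were chosen only after the result was seen. Those of neighbouring genes and of other splits of the libraries were set before.

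Among chemokines and cytokines, Cxcl1, Cxcl2 and Il1b, which attract and activate neutrophils and macrophages, had lower means in both treated groups but did not pass. Cxcl2 was 8.77 ± 13.4 CPM in Fc, 0.925 ± 0.721 in ABTAA and 0.61 ± 0.208 in VEGF Trap (SD, n = 3 per group). Log2 fold changes against Fc were -3.12 and -3.88 for Cxcl2, -2.31 and -2.54 for Cxcl1, and -1.65 and -1.73 for Il1b, with adjusted p of 0.0855 to 0.127 by edgeR. Fc 1 carried these values, and without it they were -0.14 and -0.84 for Cxcl2, -0.7 and -0.95 for Cxcl1, and -0.91 and -0.97 for Il1b (adjusted p of 0.437 to 0.962). In VEGF Trap 1 crystallin genes of the lens were high, and against Fc Cryaa stood at 3.16 ± 0.94 (adjusted p = 0.109) and Crygd at 4.23 ± 1.24 (adjusted p = 0.104), or 1.24 ± 0.99 and 2.63 ± 1.4 without this library. Without Fc 1 the inflammatory cytokine list was not called for ABTAA against Fc (adjusted p = 0.529), and without VEGF Trap 1 the lens list was not called for VEGF Trap against Fc (adjusted p = 0.369).

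Other lists did not pass between ABTAA and Fc by camera. Medians and adjusted p were 0.04 and 0.842 for tip cell and sprouting, whose mean was -0.02, 0.04 and 0.608 for VEGF ligands and receptors, 0.14 and 0.327 for junction and barrier, 0.08 and 0.428 for retinal pigment epithelium, -0.03 and 0.842 for photoreceptor, and 0.15 and 0.547 for inner retina. They were 0.27 and 0.974 for lens, -0.14 and 0.392 for ocular surface epithelium, 0.06 and 0.974 for erythrocyte, 0.33 and 0.052 for Schwann cell, -0.12 and 0.216 for interferon response, and -0.15 and 0.842 for complement. They were 0.04 and 0.608 for fibrosis and extracellular matrix, 0.01 and 0.974 for proliferation, 0.01 and 0.974 for immediate early and stress, -0.13 and 0.0658 for oxidative phosphorylation, and -0.05 and 0.216 for ribosomal protein genes. Under alternatives, Schwann cell genes passed by camera with library totals (adjusted p = 0.0393), the replicate block (0.0412) or without Fc 2 (0.00211). Oxidative phosphorylation genes passed with library totals (0.0393), and ribosomal protein genes after either GC correction (0.0181 and 0.0263). Without ABTAA 1, interferon response genes passed (1.31e-06, median -0.559), as did retinal pigment epithelium genes (0.0292, median 0.172). Summed CPM of the interferon response list was 1562.9 in ABTAA 1, 734.6 in ABTAA 2 and 1059.4 in ABTAA 3. With an estimated correlation 0 lists passed in these settings. In the other comparisons, lists not called had adjusted p of 0.0912 to 0.992 for VEGF Trap against Fc and 0.0849 to 0.81 for ABTAA against VEGF Trap. Some passed without single libraries, with medians that turned with the library left out for photoreceptor genes between ABTAA and VEGF Trap (-0.388 without ABTAA 2, -0.377 without VEGF Trap 2 and 0.602 without VEGF Trap 1) and interferon response genes (-0.451 without ABTAA 1 and 0.27 without ABTAA 2). For VEGF Trap against Fc these were endothelial, retinal pigment epithelium, photoreceptor, lymphocyte and neutrophil, cytokine and interferon response genes.

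The Fc libraries differed from both treated groups in 73 genes, and the 6 treated libraries against Fc gave 571 genes. The highest of the other splits of 9 libraries into 3 and 6, that of the libraries with replicate number 3, gave 10. Thus 1 of 84 splits gave as many, the smallest share that 84 splits can give. This argues against chance for this grouping without excluding it, and only if the 9 libraries are independent, which no label states. A GC trend as the whole cause was argued against by the correction, which kept 0.97 of the median absolute log2 fold change of the 73 genes (0.67 before and 0.65 after, with a median standard error of 0.132 in both), although 29 of the 73 passed in both comparisons afterwards. Dilution by carried-over muscle RNA as the whole cause of the lower genes was argued against, since dilution would lower all genes that muscle lacks. With library totals the 16 pigment epithelium genes, which muscle lacks, had a median of 0.03 (standard error 0.045) over both comparisons. The lower genes had -0.75 (0.044), but they were chosen from the same data for being lower, so the size of the gap decides nothing. A chromosome segment of another strain cannot be told apart, because 17 changed genes had a changed neighbour within 2 Mb where random sets had a median of 15 (permutation p = 0.34, 10000 random sets), which neither reached the upper tail nor fell to the median. An effect common to both reagents, a difference in handling of the Fc eyes, and another origin of the Fc libraries, whose headings name controls of a knockout, may each account for it and were not tested. RNA quality stays open as well and was not tested. The Fc libraries had more genes detected (16856 to 16996) than the treated ones (15968 to 16796), and Rn45s held 10.05% to 11.8% of their counts against 11.7% to 15.82%.

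For the single comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 197 genes for ABTAA against Fc (highest other 0) and 144 for VEGF Trap against Fc (highest other 0). It gave 0 for ABTAA against VEGF Trap by edgeR (711 at an unadjusted p under 0.05, DESeq2 1, highest other 2), and no split can give fewer.

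Skeletal muscle genes were higher in both treated groups, at 223 to 488 summed CPM against 108 to 165 in Fc, or at most 0.049% of counts. A GC trend as the whole cause was argued against, since the correction kept 0.94 of the median of the list, averaged over both comparisons with Fc. A candidate explanation is muscle tissue carried over into some captures. The muscle genes rose and fell together within groups, with a mean correlation of 0.56 where random lists had a 95th percentile of 0.08 (a probability of 1e-04, the smallest that 10000 random lists can give). This cannot tell carried-over tissue from regulation, since lists of other kinds varied together as much. For ABTAA against Fc, camera estimated a correlation of 0.582 for this list. It estimated 0.699 for interferon response, 0.702 for erythrocyte and 0.581 for photoreceptor genes, and less for the other lists. The list shares 0 genes with other lists, all 14 measured genes were also counted in Fc libraries, its most abundant members Tnnt3 and Acta1 reached 104 and 88.8 CPM in ABTAA, and microdissection of the lesion would be meant to exclude muscle. Whether the higher level in treated eyes came from dissection or from the reagents stays open and was not tested.

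Of 23 endothelial genes, 5 were higher in ABTAA than in Fc and 18 did not pass. The list had a median log2 fold change of 0.34, and adjusted p = 0.307 by camera with an estimated correlation. A GC trend as the whole cause was argued against, since the correction kept 0.87 of the median. A larger share of endothelial cells of unchanged kind cannot be told apart. The 23 genes differed from a common change of 0.41 by more than their errors (a probability of 2e-04 in a simulated heterogeneity test of 10000 draws), but members that other cells also express would rise less, and 0 of the 23 fell when adjusted over the list alone. Vessels brought in with muscle as the whole cause were argued against by the size of the rise. Summed CPM of the endothelial list was 2118.5 to 2706.1 in Fc and 3215.4 to 3379.7 in ABTAA, and that of the muscle list 107.7 to 165.5 and 241.3 to 488. Carried-over muscle would have had to bring more RNA of the endothelial list than of the muscle list. As a part of the cause, such vessels cannot be told apart. Within groups the endothelial and muscle totals had a correlation of 0.36 (exact permutation p = 0.329, 216 permutations), too few libraries to decide. With the muscle total as a covariate the median went from 0.34 to 0.20 and the median standard error from 0.16 to 0.29, and 0 endothelial genes passed. The covariate is higher in both treated groups. Whether muscle content accounts for part of the rise or the covariate only takes up the group difference therefore cannot be told apart. A response of endothelial cells to ABTAA may be 1 of several explanations and stays a hypothesis, as do a larger vessel share, alone or together with such a response, and the shift of the Fc libraries.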
